A study of Solanum tuberosum with 48 samples.

How the data were processed

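RNA from potato leaves was sequenced in 48 libraries, 1 for each combination of 4 cultivars (Alegria, Desiree, Milva and Saturna), 2 treatments (control and drought) and 6 experiments (F1, F3 and F4 in the field, G1, G2 and G3 in greenhouses or pots). Per the labels' protocols, homogenized leaf material of 2 to 4 replicates of a cultivar and treatment was pooled before extraction, polyadenylated RNA was selected, and the libraries were sequenced on an Illumina instrument. Each library is therefore already a mean over plants, and the spread between plants of one experiment cannot be seen.

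The submitters' processing notes name FastQC 0.11.2, RSEM 1.2.3 and Bowtie 0.12.9. The genome build and the gene annotation are not given in the sources used here. Per the file headers, each deposited table holds an expected count, a TPM value, an FPKM value and a length per gene, in the layout RSEM uses. An expected count is an estimated number of reads per gene, in which the program shares a read that fits several places among them, so the counts of near-identical genes are uncertain. The counts are not normalised, and 35.2% to 43.7% of the genes in a library had a count more than 0.001 away from a whole number. The TPM values deposited by the authors were used only as weights for the mean transcript length, and the FPKM values deposited by the authors were not used. The length deposited for a gene with several transcripts is an average weighted by transcript abundance in that library: it differed between libraries in 9788 of the 9877 genes with more than 1 transcript and in 0 genes with a single transcript.

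Every table listed the same 43034 gene IDs, of which 39021 belonged to one ID series (PGSC0003DMG) and 4013 to a second one (EPlSTUG) with a median length of 107 bases, against 1035 bases in the first. The files do not pair the IDs with gene names. None of them, 0 of 43034, matched an identifier in the RefSeq gene table of the assembly SolTub_3.0. Gene names and descriptions were therefore not used, and the 36 gene lists chosen before the data were examined, which were defined by words in gene descriptions, could not be tested.

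Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and F test, TMM normalisation factors, low counts removed by filterByExpr with a minimum count of 10, Benjamini-Hochberg adjusted p under 0.05). Log2 fold changes are given with their standard error (SE), computed as the size of the fold change divided by the square root of the F statistic. Levels are normalised read counts (CPM, the count as a share of the library total after TMM normalisation), as mean ± standard deviation (SD). For the drought effect over all cultivars, the counts of the 4 cultivars were added within each experiment and treatment, which gave 12 sums, and the experiment was the replicate block. For each cultivar, its 12 libraries were fitted with the same block. Cultivar differences, the drought effect of each experiment and the difference between experiments came from a model of all 48 libraries with 12 experiment-by-treatment terms, cultivar terms and cultivar-by-treatment terms, which left 30 residual degrees of freedom. Within an experiment the 4 cultivars are the only repeats, so p-values for single experiments and their difference do not measure the spread between plots or plantings. They rest on a single spread shared by all 48 libraries. This spread holds steady differences of a cultivar between experiments. It also holds the part of a cultivar's response that varies from experiment to experiment, since its mean response has its own term. Cultivar differences were tested against the same spread. Field and greenhouse were compared as 3 experiments against 3. The labels do not say which cultivars are drought tolerant, so each of the 3 ways to set 2 cultivars against 2 was tested.

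The pairing of control and drought libraries by experiment comes from the labels, which name the experiment of each library. The deviations of paired libraries from their group means correlated across genes with a mean r of 0.481 over 24 pairs and a lowest r of 0.0395. For 38 of the 48 libraries the best match among the 6 libraries of the same cultivar under the other treatment came from the same experiment. By leaving each library out of the cultivar means, all 48 libraries were closest to the cultivar on their label. No 2 libraries agreed within counting noise: the lowest chi-square per gene over 1128 pairs of libraries was 7.69. The 2 scalings tried moved the median log2 fold change of a comparison by at most 0.017.

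Total expected counts were 13118212 to 17376985 per library in F3 and F4 and 9195663 to 10245831 in the other 4 experiments, so the libraries fall into 2 depth batches that follow the experiment. Control and drought libraries of an experiment share a batch. Intervals and floors given for counts cover counting error only, since the reads carry no molecular identifiers. The floor for a group with no count is 3 counts over the group. A share of counts has an exact (Clopper-Pearson) 95% interval.

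The fits were tested on simulated data with 200 changed genes. This test was run after the real counts had first been fitted, and no setting was changed in response to it. For the drought effect over all cultivars (23901 genes) 58.2% of 2-fold and 90.9% of 4-fold changes were recovered, with 7 false calls. For the cultivar difference in the drought effect (22137 genes), with the changes placed in Saturna, 62.7% of 2-fold and 84.8% of 4-fold changes were recovered, with 4 false calls. For field against greenhouse in control plants (23964 genes) 1.50% of 2-fold and 63.6% of 4-fold changes were recovered, with 8 false calls, and for field against greenhouse in the drought effect (23901 genes) 0% and 45.5%, with 4 false calls. The simulations gave every experiment the same change, which the real experiments need not do. A limma 3.58.1 test on log2 gene length, run on the 6954 genes with several transcripts and at least 20 counts in every library, recovered 62.5% of shifts of 0.1 on the log2 scale placed in the cultivar difference in the drought effect, with 7 false calls.

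Comparisons, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for the drought effect over all cultivars and in each cultivar, the largest rises and falls among called genes with a log2 fold change of at least 1, the same sign in all 6 experiments and an informative description. For single experiments and for field against greenhouse it took the largest called changes, and for differences between cultivars or experiments the lowest p. For IDs with no description, as here, it allowed at most 2 risen and 2 fallen IDs. That limit was read as applying to each comparison, with the 6 experiments together and the 4 cultivars together each taken as 1 comparison, a reading made after the data were seen. Genes named outside the rule are said to be so. Alternatives were DESeq2 1.42.0, median-of-ratios size factors, no low-count filter, no replicate block, all 48 libraries with the 24 control and drought pairs as replicate block, libraries scaled to a common total before adding, only the 8 libraries of an experiment, a fold threshold of 2, and leaving out each experiment. Added after seeing the data were F3 and F4 thinned at random to the median depth of the rest, all fits without F3 and F4, each cultivar left out, the 2 Saturna libraries of F4 left out, and, for cultivars averaged over treatments, the control and drought libraries added within cultivar and experiment.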

Results

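Leaf transcriptomes were measured in 4 European potato cultivars, Alegria, Desiree, Milva and Saturna, grown with full irrigation or under drought in 6 experiments. The tissue was the terminal leaflet of the first fully grown source leaf, a leaf that exports sugar. Experiments F1, F3 and F4 were planted in the field from tubers, and G1, G2 and G3 were pot experiments started from plantlets raised in vitro. F4 and G3 were run at Groß Lüsewitz and the other 4 experiments at Potsdam. In the pot experiments watering of the drought plants stopped 12 days after the final potting, and from day 20 they received 30% of the water of the controls. From day 60 this share was 45% in G1 and G2 and 30% in G3. In F1 and F3 control ridges were drip-irrigated with 10 mm of water, and drought plants were watered later, at signs of stress in the morning. In F4 the drought plots lay under a rain-out shelter and were not watered after emergence began, while the control plots lay next to the shelter, under natural rain with added irrigation. Each of the 8 groups of cultivar and treatment held 6 libraries, 1 per experiment, and each library was a pool of 2 to 4 replicates. Total expected counts ranged from 9195663 to 17376985 per library, and 26065 to 27984 of the 43034 genes had a count.

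The experiment and the cultivar took larger shares of the differences between libraries than drought did. Of the variance of log2 CPM over 48 libraries, the experiment accounted for 38.0% (7.60% for each of its 5 degrees of freedom), the cultivar for 29.3% (9.77% for each of 3) and drought for 4.37%, with 1 degree of freedom. The part of the drought response that varied between experiments took a further 9.93% over 5 degrees of freedom (1.99% for each), and the part that varied between cultivars 1.69% over 3 (0.565% for each). Differences between cultivars that varied between experiments took 9.89% over 15 degrees of freedom (0.66% for each). The remainder held 0.455% for each degree of freedom. Component 1 of a principal component analysis held 25.2% of the variance, and the experiment explained 80.2% of its values. Components 2, 3 and 4 held 13.9%, 10.8% and 8.06%, and the cultivar explained 68.2%, 76.1% and 78.8% of their values.

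**Figure D1:**
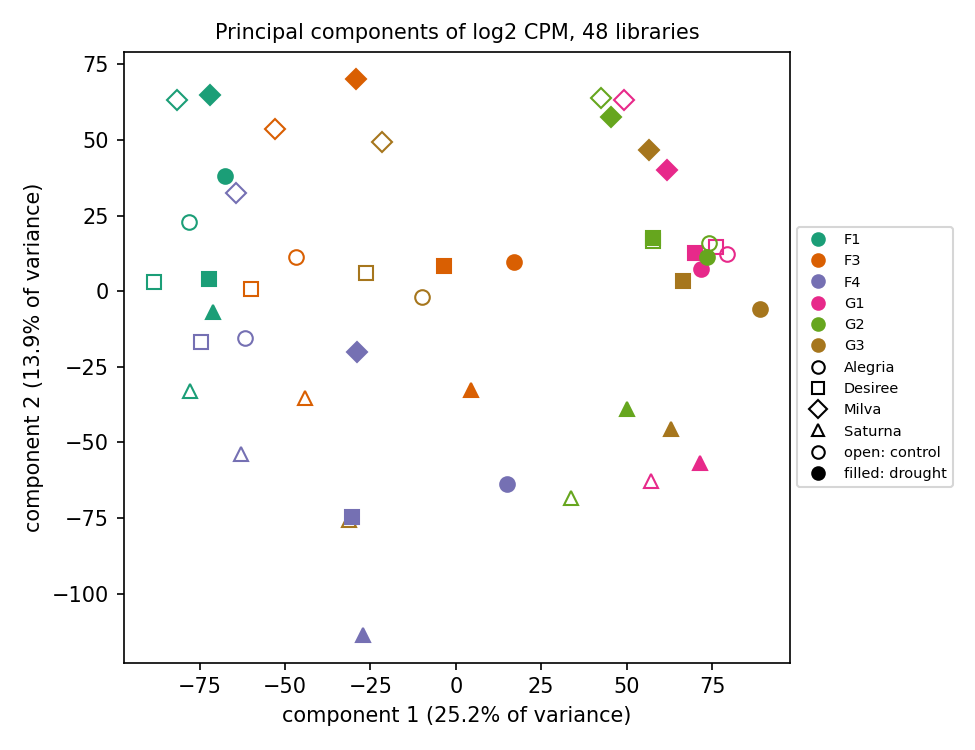
Principal components 1 (x axis) and 2 (y axis) of log2 CPM, in arbitrary units, with 1 symbol per library. Colour gives the experiment, shape the cultivar and filling the treatment. Component 1 holds 25.2% of the variance and follows the experiment, and component 2 holds 13.9% and follows the cultivar.

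The first comparison asked which genes answered to drought in the same way in all 6 experiments. No gene passed: edgeR called 0 of 23901 genes at an adjusted p under 0.05, and the lowest adjusted p was 0.294. The count at an unadjusted p under 0.05 was 3176, where 1195 would be expected by chance, and DESeq2 called 484 genes, 172 of them higher in drought. The sign of the change was the same in all 6 experiments for 8.92% of the genes tested (916 higher and 1215 lower in drought). Independent experiments would give 3.12% by chance, but the responses of certain experiments correlate, which raises this share without a response common to all 6. A fit that took all 48 libraries with the 24 pairs as replicate block, and so counted cultivars of one experiment as separate repeats, called 6156 genes.

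In the experiments taken singly, 3 genes were called in the same direction in all 6 (2 higher and 1 lower), and they are named here although they lie outside the rule for named genes and were chosen after their values were seen. PGSC0003DMG400007128 was higher in drought in 24 of 24 control and drought pairs. Its level was 30.6 ± 4.79 CPM in control and 43.0 ± 6.14 CPM in drought leaves of F1 (SD, n = 4 cultivars), and 76.4 ± 13.6 and 156 ± 18.6 CPM in G3. The log2 fold change over all experiments was 0.70 (SE 0.10), with an edgeR adjusted p of 0.294. PGSC0003DMG400023240 was also higher in 24 of 24 pairs, with a log2 fold change of 0.50 (SE 0.13, edgeR adjusted p = 0.313), and ranged from 0.20 (SE 0.08) in F4 to 1.09 (SE 0.08) in G3. PGSC0003DMG400009213, an abundant transcript, was lower in drought in 24 of 24 pairs. It went from 1140 ± 73.4 to 867 ± 46.4 CPM in F1 and from 941 ± 145 to 474 ± 12 CPM in G3 (SD, n = 4), a log2 fold change over all experiments of -0.62 (SE 0.11, edgeR adjusted p = 0.294). DESeq2 called all 3 of these genes in the overall comparison, and edgeR on the 12 sums called none of them.

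**Figure D2:**
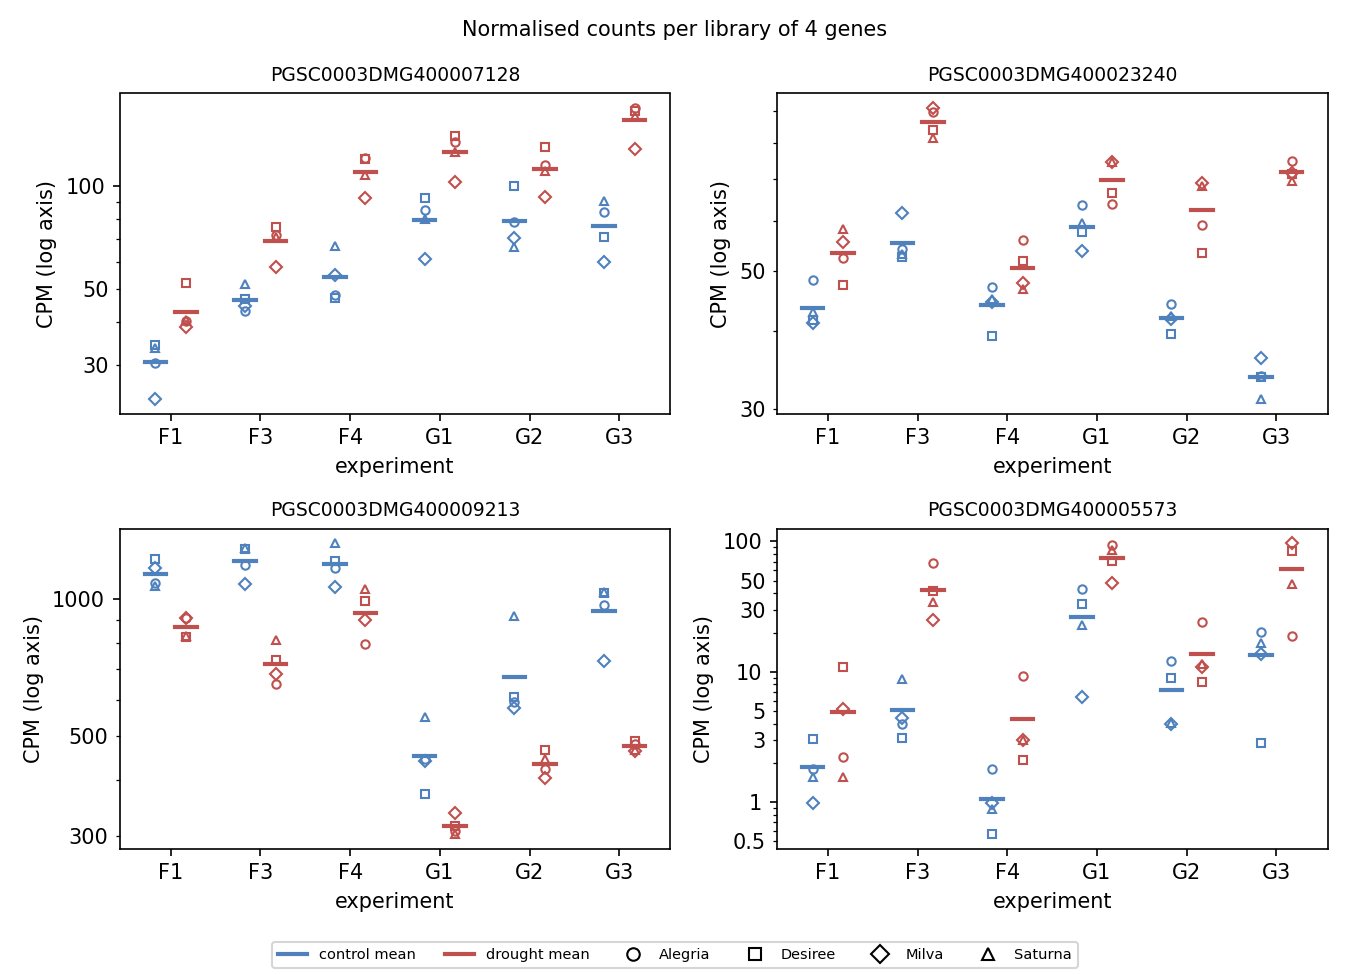
Normalised counts (CPM, log axis) of 4 genes in each of the 48 libraries, by experiment (x axis). Symbols are libraries of the 4 cultivars, bars are means of 4 libraries, blue is control and red is drought. PGSC0003DMG400007128 and PGSC0003DMG400023240 were higher and PGSC0003DMG400009213 lower in drought in 24 of 24 pairs, and PGSC0003DMG400005573 was higher in 21 of 24.

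The drought effect was then tested in each cultivar over its 6 experiments. In Milva 1 gene was called, PGSC0003DMG400005573, which rose with a log2 fold change of 2.34 (SE 0.22, edgeR adjusted p = 0.0488). The gene was higher in drought in 21 of 24 pairs over the 4 cultivars. Its log2 fold change was 1.43 (SE 0.52) in Alegria, 2.19 (SE 0.65) in Desiree and 1.54 (SE 0.22) in Saturna, none of them past the threshold, and the cultivar difference in its response had an edgeR adjusted p of 0.977. Means over the 4 cultivars were 5.08 ± 2.57 CPM in control and 42.2 ± 18.6 CPM in drought leaves of F3, and 26.4 ± 15.6 and 74.3 ± 20.1 CPM in G1 (SD, n = 4). The call in Milva was lost without F1, F3, F4, G1 or G3, and without G2 there were 2 called genes. In Alegria, Desiree and Saturna edgeR called 0 genes each, of 19518, 19495 and 19720 tested. At an unadjusted p under 0.05 there were 1987, 2360 and 2503 genes, and 2353 in Milva. DESeq2 called 121 genes in Alegria, 188 in Desiree, 263 in Milva and 271 in Saturna.

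The study's title speaks of cultivars that differ in drought tolerance, which makes the difference between cultivars in the drought response a central comparison. In the 48-library model edgeR called 0 of 22137 genes for a response that differed among the 4 cultivars, with a lowest adjusted p of 0.934, and DESeq2 called 2. The 1086 genes at an unadjusted p under 0.05 were close to the 1107 expected by chance. The model has no term for the 24 control and drought pairs, so steady differences of a cultivar between experiments enter its spread. For each degree of freedom these held 0.66% of the variance, the cultivar difference in the drought response 0.565% and the remainder 0.455%. A fit with the pairs as block was not run here, so a count near chance does not show that the cultivars responded alike. Setting Alegria and Desiree against Milva and Saturna, Alegria and Milva against Desiree and Saturna, and Alegria and Saturna against Desiree and Milva gave 0 called genes in edgeR each time, with 1312, 704 and 1529 genes at an unadjusted p under 0.05 and 1, 1 and 2 genes called by DESeq2. The labels do not say which of these pairings follows tolerance. In simulated data the 48-library fit recovered 62.7% of 2-fold changes and 41.8% of 1.5-fold changes. These changes were placed in Saturna alone and were the same in every experiment. Most 1.5-fold changes and part of the 2-fold changes were thus missed, and the pairings of cultivars were not simulated.

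Drought and control leaves differed to very different degrees in the 6 experiments, though control and drought plants stood in separate plots or blocks, so that drought and place are not separated. Of 22137 genes, edgeR called 328 in F1, 3348 in F3, 9370 in F4, 1394 in G1, 3438 in G2 and 9851 in G3. Both Groß Lüsewitz experiments, F4 and G3, had the highest counts. Higher and lower genes were balanced in F3 (1701 higher), F4 (4600) and G3 (4857), while 66.4% of the called genes were higher in G1 (926), 56.3% in G2 (1935) and 31.1% in F1 (102). Fitted on their own 8 libraries, G1 had 733 of 1142 called genes higher, G2 1176 of 2410 and F1 275 of 582, so the imbalance in G2 and F1 depends on the fit. Changes of at least 2-fold among called genes numbered 50 in F1, 761 in F3, 3066 in F4, 260 in G1, 582 in G2 and 3221 in G3.

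**Figure D3:**
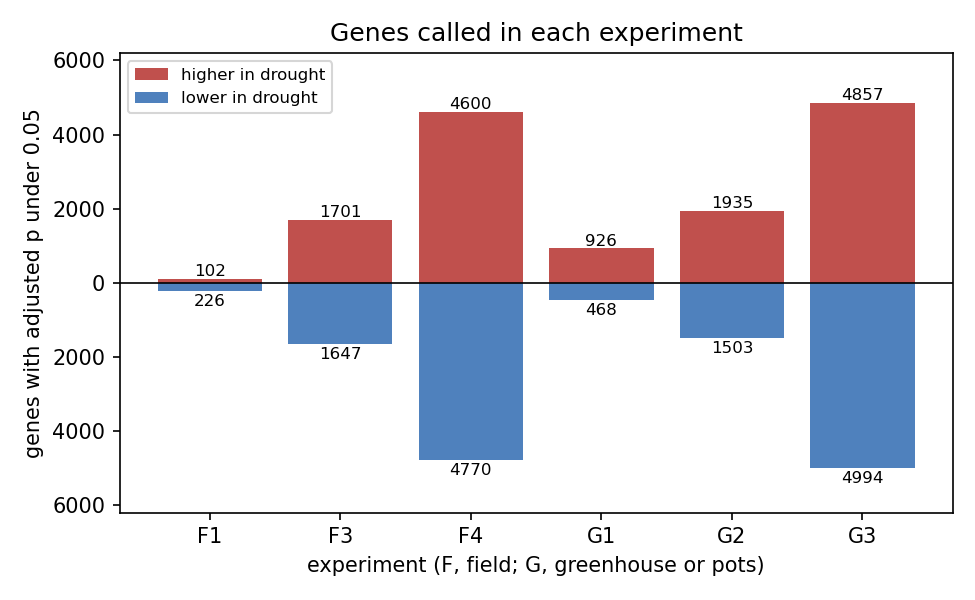
Number of genes (y axis) with an edgeR adjusted p under 0.05 for drought against control in each experiment (x axis), with genes higher in drought above 0 and lower genes below. F4 and G3 hold 9370 and 9851 called genes and F1 holds 328.

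The largest changes over the 6 experiments were between expression and near absence, in both directions. PGSC0003DMG400003530 rose in G3 from 3.17 ± 0.820 to 4310 ± 1300 CPM (SD, n = 4), a log2 fold change of 10.39 (SE 0.83, edgeR adjusted p = 1.02e-11). It also rose in F3, by 4.53 (SE 0.64), and in F4, by 7.16 (SE 1.06), but in G1 it stood at 2740 ± 1040 CPM in control and 2340 ± 519 CPM in drought leaves, with no call. PGSC0003DMG400026590 had no count in the 4 control libraries of G3 and 541 counts in the drought libraries, where it reached 13.2 ± 6.93 CPM, at least 176-fold higher. In G1 it had 22.5 ± 7.57 CPM in control leaves. Of the genes that fell, PGSC0003DMG400020673 went in F4 from 7.94 ± 5.12 CPM to no count in the 4 drought libraries, at least 163-fold lower (edgeR adjusted p = 1.56e-06). PGSC0003DMG400035772 fell in G3 from 2.18 ± 1.88 CPM to no count, at least 29.1-fold lower (edgeR adjusted p = 0.00026), from only 85 counts in the controls.

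In these tests the cultivars stood in for repeats. Without cultivar Alegria, Desiree, Milva or Saturna the F1 count was 42, 149, 10 and 45, and the G2 count 2149, 2194, 1957 and 2191. F3 gave 1389 genes without Alegria and 1372 without Desiree, and G1 784, 784 and 576 without Alegria, Desiree and Milva, while without Saturna it gave 1043. Without the cultivar block the counts were 16, 874, 5647, 512, 1159 and 6492 in F1, F3, F4, G1, G2 and G3.

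The drought response differed between experiments in 12401 of 22137 genes (edgeR, adjusted p under 0.05), and in 7948 without F4. The 2 genes with the lowest p are extreme cases and need not be typical of the 12401. PGSC0003DMG400011868 fell in F4 from 233 ± 75.0 to 4.99 ± 0.614 CPM (SD, n = 4) and rose in G3 from 4.16 ± 1.99 to 90.8 ± 71.7 CPM, with log2 fold changes of -5.51 (SE 0.35) and 4.37 (SE 0.35). PGSC0003DMG400010043 fell in F4 from 38.8 ± 9.11 to 0.705 ± 0.399 CPM and rose in G1 from 0.793 ± 0.481 to 5.57 ± 1.68 CPM and in G2 from 0.622 ± 0.171 to 3.31 ± 1.13 CPM. The edgeR adjusted p of the difference between experiments was 9.69e-15 for both. Of the 8145 genes called in at least 2 experiments, 2559 were higher in drought in 1 experiment and lower in another. The rest were called in 1 direction only.

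Drought responses were on average more alike among cultivars of the same experiment than within a cultivar across experiments. The responses (drought minus control in log2 CPM) of 2 cultivars of the same experiment correlated across genes with a mean r of 0.422 over 36 pairs. Responses of the same cultivar in different experiments had a mean r of 0.114 over 60 pairs, and responses that shared neither had 0.0942 over 180 pairs. The mean r within an experiment was 0.177 in F1, 0.478 in F3, 0.706 in F4, 0.212 in G1, 0.301 in G2 and 0.656 in G3. Responses of the same cultivar in F3 and G3 had r from 0.319 to 0.543, and in G1 and G2 from 0.272 to 0.442, both above the means within F1 and G1. Genes are not independent replicates, so no p is given for these correlations.

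**Figure D4:**
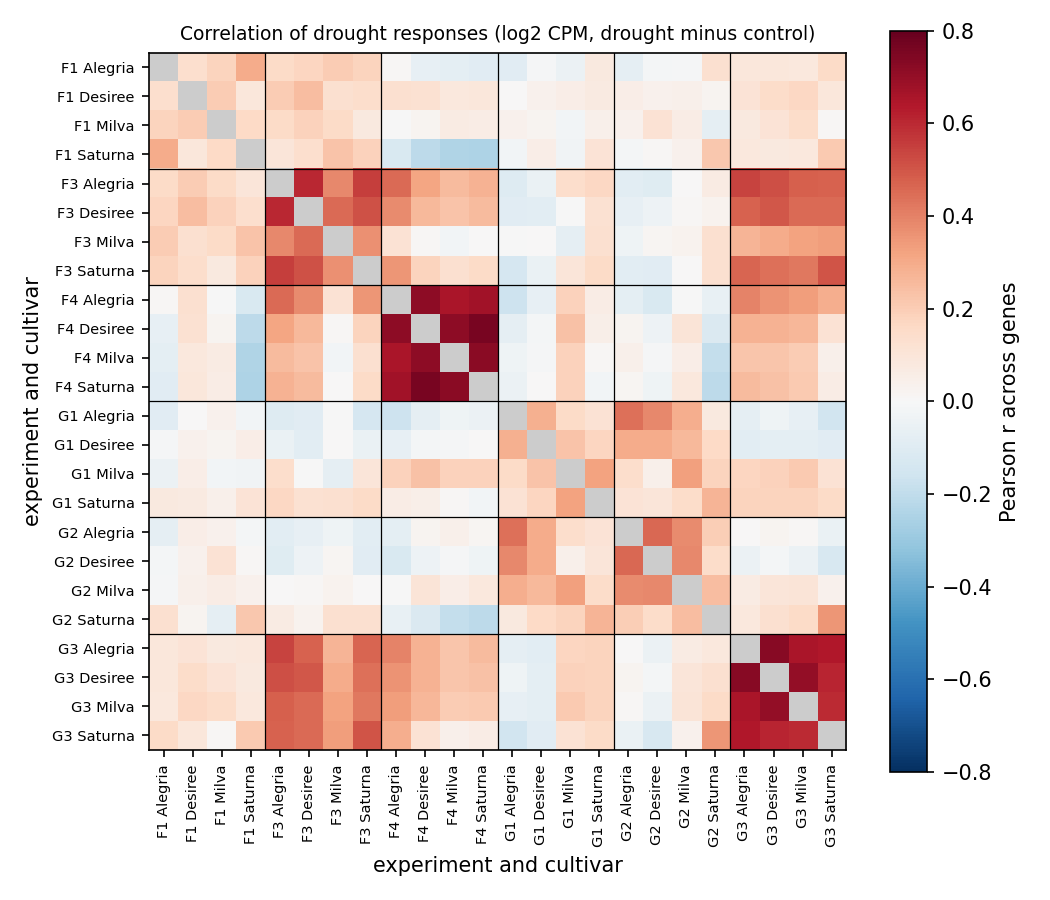
Pearson r across genes (colour, from -0.8 to 0.8) between the drought responses of the 24 combinations of experiment and cultivar, which label both axes. Grey marks the diagonal and lines part the experiments. The r within F3, F4 and G3 is at least 0.368, 0.65 and 0.599. It runs from 0.274 to 0.543 between F3 and G3, from 0.0387 to 0.442 between G1 and G2, and from 0.0381 to 0.394 between F4 and G3.

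Certain experiments shared part of their response. The log2 fold changes of F3, in the field at Potsdam, and G3, in pots at Groß Lüsewitz, correlated across genes with r = 0.62, and they shared 1193 higher and 1219 lower called genes, where independent lists would share 373 and 372. G1 and G2 had r = 0.42 and shared 663 higher and 302 lower genes against 81 and 32, with 0 genes called in opposite directions. F4 and G3 had r = 0.33 and shared 1693 higher and 1923 lower genes against 1009 and 1076, and a further 1155 genes were called in opposite directions, against 2084 for independent lists. F3 and F4 had r = 0.32 and F1 and F3 r = 0.35. F4 and G2 had r = -0.029, with 1070 genes called in opposite directions, 267 shared higher and 337 shared lower, where independent lists would give 729, 402 and 324. Over all 6 experiments 17 genes were called higher and 28 lower in at least 5, where independent lists would give 0.352 and 0.208. The 6 lists come from the same fit, in which a gene has the same spread in each, and certain responses correlate. Both raise such counts, so the excess alone does not show a response common to all 6. The shared spread bears on the overlaps between pairs of experiments as well.

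Cultivars differed in the level of many genes. Averaged over treatments, edgeR called 17648 of 22137 genes, in a fit that counts the control and drought libraries of a cultivar in 1 experiment as separate repeats. With these libraries added, so that the experiment is the repeat, 16901 genes were called, 16191 of them among the 17648, and a model without the replicate block called 9391. Between 2 cultivars the count ran from 9585 for Alegria against Desiree to 11728 for Milva against Saturna, of which 2844 differed at least 2-fold and 168 by at least 5 on the log2 scale. PGSC0003DMG400019330 was a transcript of Milva, with 15.0 ± 2.92 CPM there (SD, n = 12) and 0.0480 ± 0.0656, 0.0376 ± 0.0486 and 0.121 ± 0.0881 CPM in Alegria, Desiree and Saturna (edgeR adjusted p = 1.76e-29). PGSC0003DMG400017101 was higher in Milva too, at 49.0 ± 17.9 CPM against 4.99 to 5.38 CPM in the rest. PGSC0003DMG400000655 was low in Saturna, at 6.32 ± 1.92 CPM against 205 ± 44.4 in Alegria, 126 ± 21.2 in Desiree and 131 ± 16.8 in Milva (edgeR adjusted p = 7.29e-28). PGSC0003DMG400002582 had 0.0862 ± 0.127 CPM in Saturna and 21.7 ± 2.88 CPM in Milva. A low count in 1 cultivar can also arise where its sequence differs from the reference that the reads were matched to.

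Field and pot experiments differed in control leaves, with wide uncertainty from 3 experiments on each side. Planting from tubers or from plantlets raised in vitro follows the setting, so they cannot be told apart. Both experiments of the deeper batch, F3 and F4, were in the field, so setting and batch overlap as well. Of 23964 genes, edgeR called 1639, with 953 higher in the field. PGSC0003DMG400020686 was higher in the field, at 19.4 ± 6.88 against 0.215 ± 0.11 CPM (SD, n = 3 experiments), a log2 fold change of 6.52 (SE 0.46, edgeR adjusted p = 0.0322). PGSC0003DMG400027840 had 50 counts in the 12 field control libraries and no count in the 12 greenhouse ones, at least 12.1-fold higher. PGSC0003DMG400024003 was lower in the field, at 3.13 ± 4.07 against 495 ± 352 CPM. PGSC0003DMG400047292 had no count in the field controls and 42 in the greenhouse controls, all 42 in the 3 Desiree libraries. The count of called genes changed with each experiment left out. It was 0 without F1, F3, G1 or G2 and 1 without F4, and it rose to 5187 without G3, the pot experiment whose plants were moved to the rain-out shelter, with 1634 of the 1639 genes among them.

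For a difference between field and pots in the drought response itself, edgeR called 0 of 23901 genes, with 1846 at an unadjusted p under 0.05 against 1195 expected by chance, and DESeq2 called 138. In simulated data this fit recovered 0% of 2-fold and 45.5% of 4-fold differences, so smaller differences were not detectable with 3 experiments on each side.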

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

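The tests of depth, batch, single cultivars, noise, setting, site and the second ID series, and the counts at an unadjusted p in other splits, were chosen after the results were seen, while those of gene length and of called genes in other splits were set before their own values were computed but with the counts of called genes known.

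The first pattern is that 12401 genes had a drought effect that differed between the 6 experiments. Depth does not account for it: with F3 and F4 thinned to the depth of the rest the count was 11959. The deeper batch of F3 and F4 is not needed for it either, since 6795 genes differed among F1, G1, G2 and G3, which share a depth, though F4 alone carries much of the count, which was 7948 without it. The lowest count without 1 of the cultivars was 8903, and a smooth trend on gene length explained at most 0.727% of the variance of the log2 fold changes in F4 or G3. What stays open is whether the experiments differ in biology (duration and depth of the drought, plant age, weather) or in plot: control and drought plants stood in separate blocks, and in F4 the control plots lay outside the shelter, so drought and place cannot be told apart within an experiment.

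The second pattern is that the responses of some pairs of experiments resembled each other more than others: corrected for the reliability of each response, r over the 15 pairs ran from -0.085 for F4 and G2 to 0.87 for G1 and G2, with 0.78 for F3 and G3. The corrected r starts from mean differences in log2 CPM, while the r between experiments given above comes from edgeR fold changes. The corrected values therefore differ from the earlier ones by more than the correction. Noise in weak responses is argued against as the whole cause, since F4 and G2, with reliabilities of 0.905 and 0.627, had the lowest r, and since the lowest corrected r within the sets F3, F4, G3 and G1, G2 exceeded the mean between them by 0.31. Those sets were picked from the same correlations, and F1 belongs to neither, with a corrected r of 0.55 with F3, 0.31 with G3 and -0.081 with F4. Field or greenhouse setting did not sort the experiments better than all other splits 3 against 3. Of the 10 ways to split them, 3 gave as high a difference of mean r within and between. For site, 6 of the 15 ways to pick a pair of experiments gave as high a difference. Mean r was still higher within settings than between by 0.0512, and within sites by 0.0224, so a part played by either is not excluded. G1 and G2 share setting, site and water shares, while F3 and G3 share neither setting nor site. A candidate explanation that stays untested is the severity or timing of the drought at harvest, which the labels do not give for each library.

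The third pattern is that in the drought library of Saturna from F4, 1.44% of the counts (exact 95% interval 1.43% to 1.44%) fell on the second ID series, far from the next value of its group, 0.304%, while its control partner had 0.515%, the highest of the other 47 libraries. It was 1 far value among 24 tests of 8 groups on 3 measures, where chance gives about 1 in 20, and its gap to the next value took 92.2% of the range of its group. Depth is not the cause, since the deepest library had 0.300%, and a drought response of Saturna in general is argued against, since the share was higher in drought in 3 of the other 5 experiments. The excess lay in 4 features, EPlSTUG00000001731, EPlSTUG00000000051, EPlSTUG00000003166 and EPlSTUG00000001640, at 3.19 to 6.43 times their mean in the other 7 libraries of F4. Without them the share was 0.0788%, near the top of the 0.0368% to 0.0806% of those libraries, which had 0.296% to 0.515% with them. The features were picked as the largest and held most of the series in those libraries too, so their removal was bound to bring the shares closer. The files do not say what these features are, so a difference in RNA selection and a true change of these transcripts stay open, and no other biological explanation was tested.

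Among the genes already named, several had a drought response that differed between experiments in the edgeR test, as it did for 12401 of 22137 genes. Their adjusted p was 0.00266 for PGSC0003DMG400007128, 1.54e-07 for PGSC0003DMG400023240 and 0.00278 for PGSC0003DMG400009213, the 3 genes called in the same direction in all experiments. It was 3.73e-10 for PGSC0003DMG400003530, 6.83e-05 for PGSC0003DMG400026590, 0.000132 for PGSC0003DMG400020673, 0.0423 for PGSC0003DMG400035772, and 9.69e-15 for PGSC0003DMG400011868 and PGSC0003DMG400010043. PGSC0003DMG400011868 and PGSC0003DMG400010043 were chosen for the lowest p in this same test, so a low value was certain for them. PGSC0003DMG400003530, PGSC0003DMG400026590, PGSC0003DMG400020673 and PGSC0003DMG400035772 were chosen for the largest change in a single experiment of the same model. That choice favours a low value for them too, so it is no independent evidence. In the length column, which the comparisons above do not use, the abundance-weighted length of 180 of 6954 genes differed between drought and control in G3 (limma, adjusted p under 0.05), 131 of them longer in drought.

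Other splits of the same libraries show where chance can be excluded. For the cultivar difference averaged over treatments the real labels alone, 1 of 40 shufflings of cultivars within experiments, gave 17648 genes, and the highest other count was 6339. For the difference between experiments the real labels alone, 1 of 40 swaps of treatment within pairs, gave 12401 genes against at most 5425, a high count since a swap keeps the size of each response. These swaps stand for no steady drought response in any pair. They do not stand for a response shared by all experiments, so they do not test the difference against that case. In Milva 1 of 32 swaps of treatment within experiments gave 1 gene, the real one, and the rest 0, which excludes chance only if the 4 cultivars are not counted as 4 tests. Counts of 0 in edgeR cannot be tested in this way, since no split can call fewer: all 32 swaps gave at least 0 for the drought effect over all cultivars, in Alegria and in Desiree, where the highest other count was 0, and in Saturna, where it was 1, and all 40 shufflings gave 0 for the cultivar difference in the drought effect and its 3 pairings. For field against greenhouse the 10 splits are too few for a share under 0.05: in control leaves the real split alone (1 of 10) gave 1639 genes and the others 0, and for the drought effect all 10 gave 0. For single experiments, fitted on their own 8 libraries, the 8 splits that put 1 library of each cultivar on each side are also too few: the real one alone (1 of 8) gave 582 genes in F1, 4073 in F3, 8877 in F4, 1142 in G1, 2410 in G2 and 6949 in G3, and the others 0. A further 24 splits put both libraries of a cultivar on the same side, so that only 2 cultivars inform the test, and gave at most 2 genes in F1, 5 in G2 and 0 in the other 4 experiments.

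The same splits were then read by the count of genes at an unadjusted p under 0.05. The real split gave the most genes for the drought effect over all cultivars, by a small margin (3176 genes, 1 of 32 splits, against at most 2925), and in Milva (2353, 1 of 32, against at most 1770). A share of 1 in 32 is the smallest that these splits can give and excludes chance for a test taken alone, but not once the 5 tests of this kind are allowed for. Chance is not excluded in Alegria (1987 genes, 4 of 32 splits with as many), Desiree (2360, 2 of 32) and Saturna (2503, 2 of 32), where other splits reached 3698, 2966 and 3292. The highest other split set G1 and G2 against the remaining 4 experiments over all cultivars, in Alegria and in Desiree, and F4 against the rest in Saturna. For field against greenhouse in the drought effect 2 of 10 splits gave 1846 genes or more, the highest, with 3819, setting F1, G1 and G2 against F3, F4 and G3, and 10 splits are too few for a share under 0.05. For the cultivar difference in the drought effect and its 3 pairings the real labels gave the most genes each time (1 of 40 shufflings): 1086 against at most 235, 1312 against 511, 704 against 484 and 1529 against 495. That comparison decides nothing, because every shuffling lies below the 1107 genes that chance gives: it moves the constant differences between cultivars into the spread.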

How the results depend on the processing

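The thinning, the fits without F3 and F4, the fits without a cultivar, those without the Saturna libraries of F4 and the one with control and drought libraries added were chosen after seeing the data. Of 239 recomputed counts of called genes, 180 stayed within 1.5 times the reported count and 59 did not. Of 229 recomputed values of named genes, 193 kept direction and side of the threshold, 30 lost and 6 gained the call, and 0 reversed. Except where stated, the cause of a change was not tested. DESeq2 called 629 genes in F1 (328 in edgeR), 4882 for field against greenhouse in control leaves (1639), and, where edgeR called 0 or 1, 484 over all cultivars, 121 in Alegria, 188 in Desiree, 263 in Milva, 271 in Saturna, 138 for field against greenhouse in the drought effect, 2 for the cultivar difference in it and 1, 1 and 2 for the 3 pairings of cultivars. With no low-count filter F1 had 195 genes and Saturna 3. With only its own 8 libraries F1 had 582. Median-of-ratios size factors left every count within 1.5 times. Taking all 48 libraries with the 24 pairs as replicate block gave 6156 genes for the drought effect over all cultivars in place of 0, since cultivars then count as repeats. With no replicate block 0 genes were called in Milva, 9391 for cultivars averaged over treatments (17648), 6602 for the difference between experiments (12401), and 16, 874, 5647, 512, 1159 and 6492 in F1, F3, F4, G1, G2 and G3. Without the block the counts of 0 over all cultivars, in Alegria, Desiree and Saturna, for the cultivar difference in the drought effect, its 3 pairings and field against greenhouse in the drought effect stayed at 0. That alternative was not run for single cultivars or pairs of cultivars compared with each other, or for field against greenhouse in control leaves, which has no block. Without F3 and F4 there were 141 genes in F1, 6795 for the difference between experiments, 1 for Alegria and Desiree against Milva and Saturna, 0 for control leaves of field against greenhouse and 0 in Milva. That fit holds fewer libraries. Leaving out each cultivar gave 10 to 149 genes in F1, 1372 to 2956 in F3, 576 to 1043 in G1 and 1957 to 2194 in G2. Leaving out each experiment or cultivar gave 7948 (without F4) to 12308 for the difference between experiments. Leaving out each experiment gave 0 to 5187 for control leaves of field against greenhouse (5187 without G3, 1 without F4), 0 to 2 in Milva (2 without G2), 0 to 2 in Saturna (2 without F1), 0 to 1 for field against greenhouse in the drought effect (1 without F4) and 0 to 1 for Alegria and Desiree against Milva and Saturna (1 without F4). The tests of 36 gene lists, with their alternatives, were not run, since no gene ID could be paired with a description. Depth can limit genes with few counts, which was not tested on its own. Thinning F3 and F4 to the depth of the rest kept every count within 1.5 times. Leaving out the Saturna libraries of F4 did so for the counts of the 48-library model, the only ones refitted that way.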

Other observations

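The tests on component 1 and on transcript length were chosen after the results were seen, while those on response size by cultivar and on left-out experiments were set before their own values were computed.

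Along component 1, drought leaves of the pot experiment G3 sat where all leaves of G1 and G2 sat. The mean of component 1 was -22.2 ± 9.19 in control and 68.8 ± 14.1 in drought leaves of G3 (SD, n = 4 cultivars), 65.4 ± 14.6 and 68.7 ± 4.69 in G1, and 52.1 ± 17.8 and 56.7 ± 12.3 in G2. In F3 it was -50.9 ± 7.14 in control and -2.76 ± 19.5 in drought leaves, in F4 -65.9 ± 5.84 and -17.8 ± 22.0, and in F1 -81.5 ± 4.87 and -70.6 ± 2.20. A hypothesis is that drought in F3, F4 and G3 moved leaves along an axis that also parts the control leaves of G1 and G2 from those of F1. The control difference between G1 and G2 and F1, which shares no library with the other 3 experiments, correlated across genes with the drought response with r = 0.60 in F3, 0.38 in F4 and 0.57 in G3. Compared within each cultivar, r was at least 0.24 in F3, 0.22 in F4 and 0.29 in G3, and the mean was 0.42, 0.33 and 0.42. What the axis is was not tested: plant age, pot culture and indoor climate all differ between G1, G2 and the field, and a set of genes that vary under many conditions may give such an r as well.

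Genes picked from 5 experiments mostly kept their direction in the sixth, except in F4. Of the 500 genes with the lowest p in the other 5 experiments, 91.0% had the same sign in G3, 85.2% in F3, 79.4% in G1, 74.8% in G2 and 70.2% in F1, but 51.2% in F4. The median change in that direction on the log2 scale was 1.00 in G3, 0.47 in F3, 0.33 in G1, 0.32 in G2, 0.14 in F1 and 0.03 in F4. In the 5 experiments used for the choice it was 0.63 to 0.81. F3 and G3 resemble each other, as do G1 and G2, so each of these had a similar experiment among the 5. So a drought set shared by all 6 experiments is left undecided, with F4, where the controls stood outside the shelter, as the clearest exception.

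Cultivars could not be ranked by the size of their response. The SD of the drought response over 11224 genes, averaged over 6 experiments, was 0.609 ± 0.271 in Alegria, 0.573 ± 0.210 in Saturna, 0.564 ± 0.228 in Desiree and 0.518 ± 0.178 in Milva (SD, n = 6). These means spanned 16.2% of their average, and a permutation test of cultivars within experiments with 100000 resamples gave p = 0.181. The experiments differed more, from 0.345 ± 0.0340 in F1 to 0.883 ± 0.0687 in G3 (SD, n = 4).

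The mean transcript length, weighted by abundance, was higher in drought in all 6 experiments on average over cultivars. The difference was 75.3 ± 11.7 bases in F4 (from 1278.5 to 1353.8 bases), 27.2 ± 35.6 in G3, 19.5 ± 30.3 in F3, 12.4 ± 21.9 in F1, 8.30 ± 21.2 in G2 and 0.178 ± 27.4 in G1 (SD, n = 4). Outside F4 the difference was smaller than the spread between cultivars, and 18 of 24 pairs were longer in drought, so the hypothesis that drought raises the mean transcript length, in 6 of 6 experiments, may rest on F4, the only case beyond that spread. In the test of length per gene, G3 and not F4 had the most: 180 of 6954 genes differed in G3 (131 longer in drought) and 67 in F4 (37 longer). A further 9 genes differed in F1, 1 in F3, 4 in G1 and 5 in G2. The count was 0 for the cultivar difference in the drought effect (limma, 296 at an unadjusted p under 0.05), while 1723 genes differed between cultivars averaged over treatments.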
